A study of Mus musculus with 6 samples.

How the data were processed

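Gene expression was measured by RNA sequencing of lung tissue from C57BL/6 mice in 3 groups of 2 libraries each: saline controls (Control), monocrotaline (MCT), and monocrotaline with C75 (MCT_C75). Per the labels' protocols, RNA was extracted with Trizol and ribosomal RNA was depleted from 3 μg of RNA before library preparation, so that long non-coding RNAs without a poly(A) tail were retained. Whether the libraries kept strand information, and which aligner was used, is not given in the sources used here. The submitters' processing notes name the mm10 genome build and HTSeq (given there as version 6.0), a read counter, without stating its settings.

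The authors deposited 1 table of 48897 genes with raw read counts per library and, beside them, RPKM values (reads scaled by gene length and by the library's total). The deposited counts are whole numbers and were used for all tests. The deposited RPKM values could be recomputed from each count, the gene length in the table and the column total, and were not tested. No row lacked a gene name. Column names were matched to the sample titles. Gene symbols, positions and gene types came from the same table. Positions are given as deposited, on mm10 per the submitters' processing notes.

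Column totals ranged from 60737547 to 77319458 counts, and 34107 genes had a count in at least 1 library. Counts were scaled with edgeR's TMM factors and reported as CPM, counts scaled to a common library size. Genes were kept by edgeR's filterByExpr on the 3 groups, which left 23399. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with group as the only factor, fitted to all 6 libraries so that the 3 groups shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over the tested genes with a threshold of 0.05. Unless another tool is named, genes called or passing over all genes are those of edgeR. Standard errors are the log2 fold change divided by the square root of F, and intervals are 95% intervals. The common biological coefficient of variation was 0.28. The labels do not say whether the libraries of a group came from single or pooled animals, so p-values measure the spread between these samples.

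Gene lists (39 lists with 579 symbols, of which 576 matched the table) were fixed before the files were seen, as were the design, the rule for naming genes and all but 1 of the alternatives. Each list was tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 39 lists of a comparison, and again with an estimated correlation. The second version also relies on the few residual degrees of freedom that 6 libraries in 3 groups leave, so it could hardly call a list here. Named genes were the 6 largest rises and 6 largest falls past the threshold with at least 1 CPM in the higher group and no overlap between groups, the 3 largest such long non-coding RNAs in each direction, the 3 members of smallest p from each list that passed camera, and 7 genes named in advance for their link to C75 or to pulmonary hypertension. Where no gene passed, the 5 genes of smallest p were named. Clone names were left out of the first of these sets. Other genes named below were chosen after their values were seen.

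The procedure was tested on simulated counts drawn from the real library sizes and gene means, with their estimated dispersions, and with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with a mean of at least 1 CPM, so the shares recovered do not describe genes below that level. In the simulation of MCT against Control, over 22671 genes, 41% of the 2-fold and 92% of the 4-fold changes were recovered, with 16 false calls. In that of MCT_C75 against MCT, over 22654 genes, the shares were 45% and 84%, with 7 false calls. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, other thresholds, a replicate block, the 4 compared libraries alone and each library of the compared groups left out in turn. A fit without Control replicate 2 and MCT_C75 replicate 2 was added after the data had been seen. No reference genome was used here, so no sequence was examined.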

Results

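Lungs of C57BL/6 mice were profiled 5 weeks into treatment. Monocrotaline is a plant alkaloid that injures the pulmonary vasculature and is used to induce pulmonary hypertension in rodents. C75 is a synthetic inhibitor of fatty acid synthase. Mice were 8 weeks old at purchase, MCT was given at 60 mg/kg and C75 at 2 mg/kg. The labels disagree on the route and number of MCT injections, so neither is stated here. C75 was dissolved in 0.5% DMSO and no DMSO is named for the other groups, so its effect cannot be separated from that of the solvent. Each of the 3 groups held 2 libraries, with column totals of 60737547 and 77319458 counts in Control, 72137257 and 67910019 in MCT, and 66260242 and 68629010 in MCT_C75.

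Across all tested genes the correlations did not separate the libraries by group. Pearson correlations of log2 CPM across genes ranged from 0.966 to 0.977, with a mean of 0.972 within groups and 0.971 between groups. Of the 15 ways to pair the 6 libraries, 5 gave a within-pair mean as high as the real one, and the design cannot give a share below 0.0667. The first principal component, with 25.8% of the variance, placed the Control libraries at opposite ends. The second, with 22.1%, set Control (-44.8 and -35.6) apart from MCT (48.7 and 11.3). The MCT_C75 libraries lay far apart on it, at 45.9 and -25.6.

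The first comparison asked which lung transcripts differed after monocrotaline. Genes typical of neutrophils were lower in MCT than in Control lungs. S100a8 and S100a9, which encode the subunits of calprotectin, an abundant neutrophil protein, fell by 2.43 (SE 0.23) and 2.44 (SE 0.22) on the log2 scale, and S100a9 was at 139 ± 3.41 CPM in Control and 25.6 ± 0.894 CPM in MCT (mean ± SD, n = 2 each). Mmp8, the neutrophil collagenase, fell by 2.19 (SE 0.21). The only gene that rose was Rnu1a1, a U1 small nuclear RNA of the spliceosome, at 226 ± 33.3 CPM in Control and 669 ± 6.99 CPM in MCT (log2 fold change 1.56, SE 0.22).

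In all, edgeR's quasi-likelihood test called 12 of 23399 genes, 1 higher and 11 lower in MCT. Besides those above, Slfn4 (log2 fold change -2.57, SE 0.23), Dhrs9 (-2.55, SE 0.31) and Clec4e (-2.54, SE 0.32) had the largest falls, followed by Clec4d, Cxcr2, Gm38525, Retnlg and Ccr1 at -2.02, -2.02, -1.94, -1.87 and -1.56. Benjamini-Hochberg adjusted p-values of edgeR were 0.00146 for Slfn4, S100a8, S100a9 and Mmp8, 0.0111 for Dhrs9, 0.0132 for Clec4e and 0.0288 for Rnu1a1. S100a9 lies on chromosome 3 at 90692630 to 90695721, S100a8 on chromosome 3 at 90669071 to 90670034, Mmp8 on chromosome 9 at 7558429 to 7568486 and Slfn4 on chromosome 11 at 83175172 to 83190216. Rnu1a1, on chromosome 11 at 87422867 to 87423030, lies inside the gene Tex14 on the same strand, so the counts of the 2 could be shared. DESeq2 called 108 genes, 21 higher and 87 lower, and limma-voom 15, 2 higher and 13 lower. An unadjusted edgeR p under 0.05 was found for 1076 genes, where chance gives 1170. Calls nearly vanished when either MCT library was left out and multiplied when either Control library was. Without Control replicate 1 most of them were higher in MCT, the reverse of the main result. Each of these fits leaves a group with 1 library.

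**Figure D1:**
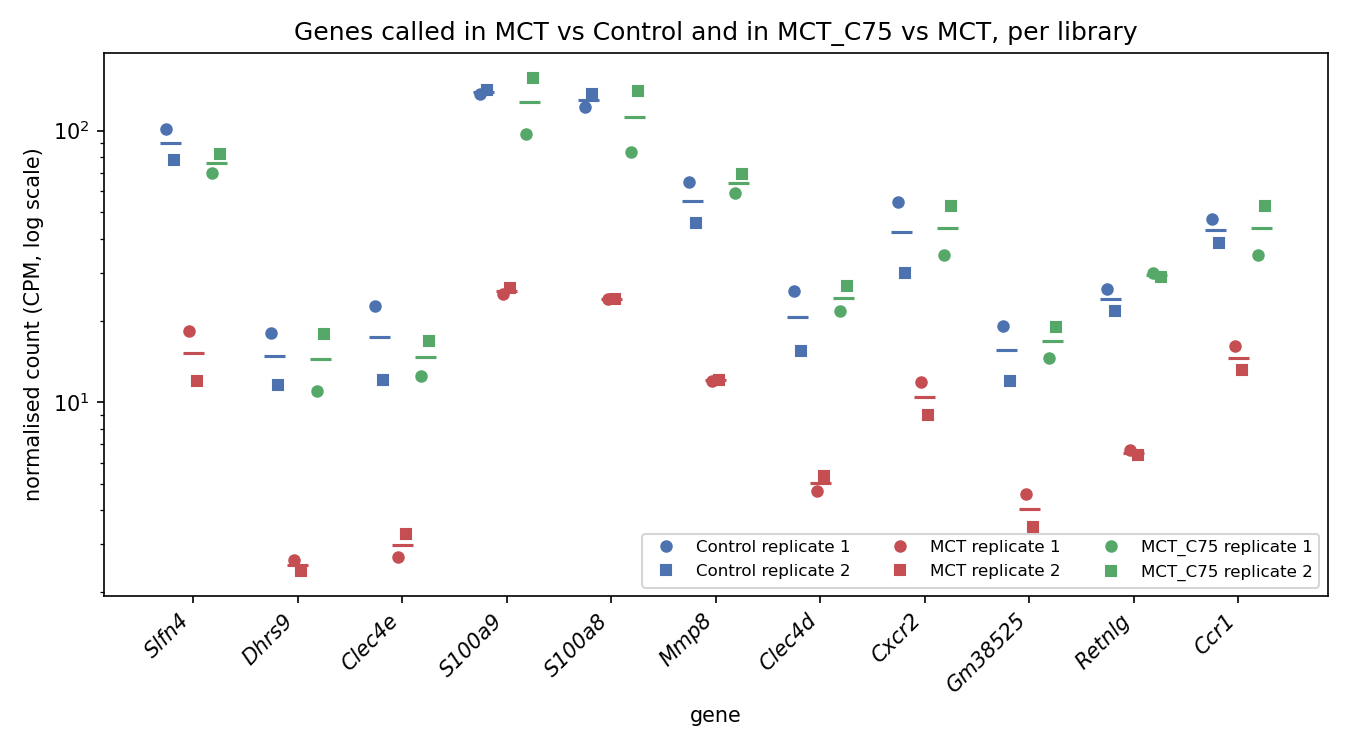
Normalised counts (CPM, log scale) per library of the 11 genes called both in MCT vs Control and in MCT_C75 vs MCT, with circles and squares for replicates 1 and 2 and short bars for group means. Both MCT libraries lie below all 4 other libraries for each gene, as for S100a9 at 25.6 CPM in MCT against 139 in Control and 127 in MCT_C75.

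Of the 14 neutrophil genes fixed in advance, 6 fell, and 11 fell when adjusted over the list alone. The list median was -1.94 (camera adjusted p = 1.19e-15; adjusted p = 0.814 with an estimated correlation), and it stayed between -2.11 and -1.35 with any Control or MCT library left out. Ngp, Camp and Ltf, granule genes transcribed mainly in neutrophil precursors, had values of 0.06, -0.14 and 0.18 and did not pass. Red cell and blood transcripts were also lower by camera (median -2.26, adjusted p = 1.02e-05; adjusted p = 0.912 with an estimated correlation), with 0 of 11 members called over all genes and 8 lower when adjusted over the list alone. Without Control replicate 2, the median of the red cell list was -1.27 (adjusted p = 0.0288). The haemoglobin share varied widely within groups, at 0.0901% and 0.348% of counts in the Control libraries, 0.0204% and 0.0276% in MCT and 0.0143% and 0.0519% in MCT_C75. Hbb-bs and Alas2, a haem synthesis enzyme, had log2 fold changes of -3.27 (SE 0.62) and -2.83 (SE 0.48) and did not pass.

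Extracellular matrix genes were higher as a list in MCT (median 0.50, camera adjusted p = 2.25e-05; adjusted p = 0.912 with an estimated correlation). None of the 23 members passed over all genes in edgeR, and 5 were higher when adjusted over the list alone. The median was 0.30 without Control replicate 2 and 0.75 without Control replicate 1, and the camera call held with any Control or MCT library left out. Col1a1, the main chain of type I collagen, had a log2 fold change of 1.22 (SE 0.29), and Loxl1 and Eln, for elastic fibre assembly, had 0.80 (SE 0.19) and 0.80 (SE 0.22). The cell cycle list was higher (median 0.66, camera adjusted p = 0.0016; adjusted p = 0.912 with an estimated correlation) with 0 of 20 members called, but the median was 0.00 (adjusted p = 0.754) without MCT replicate 2, in which Mki67 stood at 85.9 CPM against 34.1 CPM in MCT replicate 1. Alveolar type 1 genes were higher (median 0.26, camera adjusted p = 0.0167; adjusted p = 0.912 with an estimated correlation), with Gprc5a at 0.51 and 0 of 12 members called over all genes or over the list alone, and the median was 0.09 (adjusted p = 0.462) without Control replicate 2 and 0.46 without Control replicate 1.

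Further lists were lower in MCT by camera, with no member called over all genes in edgeR. Over the list alone, 3 members were lower for inflammatory cytokines and chemokines, 1 for interferon response and 0 for the others. They were inflammatory cytokines and chemokines (median -0.53, adjusted p = 0.0009), T and NK cells (-0.36, 0.0098), immediate early and heat shock genes (-0.41, 0.0155), interferon response (-0.28, 0.0155) and mesothelium (-0.50, 0.0167), and each had an adjusted p = 0.912 with an estimated correlation. The smallest edgeR p-values among their members belonged to Il1b, which encodes interleukin-1 beta (-1.99, SE 0.30), Rsad2 (-1.32, SE 0.31), Junb (-0.85, SE 0.24), Klrb1c (-0.68) and Bnc1 (-1.08), none past the threshold in edgeR. Without Control replicate 2 the camera adjusted p was 0.358 for inflammatory cytokines and chemokines, 0.78 for interferon response and 0.633 for mesothelium, and without Control replicate 1 it was 0.432 for T and NK cells and 0.422 for immediate early and heat shock genes, whose median then was 0.07. Leaving out 1 library also moved the medians, to -0.12 (Control replicate 2) and -0.91 (MCT replicate 1) for inflammatory cytokines and chemokines, -0.07 (Control replicate 1) for T and NK cells, -0.16 (Control replicate 2) and -0.51 (Control replicate 1) for interferon response, and -0.24 (MCT replicate 1) and -1.73 (MCT replicate 2) for mesothelium.

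The remaining 29 lists did not pass camera. The lists closest to the disease had these medians: heritable pulmonary hypertension genes 0.03 (camera adjusted p = 0.744), vasoactive mediators 0.08 (0.41), smooth muscle contractile genes 0.17 (0.182), endothelial cells -0.07 (0.826), hypoxia response -0.12 (0.287), p53 and DNA damage response -0.03 (0.501) and oxidative stress and xenobiotic response -0.03 (0.495). Of the 15 smooth muscle contractile genes, 14 had a positive log2 fold change and 0 were called. The metabolic lists had medians of -0.07 for fatty acid synthesis (0.362), 0.01 for fatty acid oxidation (0.961, mean -0.01), -0.04 for cholesterol synthesis (0.495) and -0.10 for glycolysis (0.388). The smallest adjusted p among lists that did not pass was 0.0588, for thymus and lymphoid organ, whose median was -0.39 and mean 0.01.

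Fasn, the target of C75, did not differ past the threshold in any comparison. Its mean was 662 ± 18.3 CPM in Control, 739 ± 42.1 CPM in MCT and 727 ± 120 CPM in MCT_C75 (n = 2 each), and its fold change had a 95% interval of 0.852 to 1.46 for MCT vs Control and 0.751 to 1.29 for MCT_C75 vs MCT. Cpt1a, the rate-limiting carnitine palmitoyltransferase of fatty acid oxidation, and Acaca, which makes the malonyl-CoA used by Fasn, had log2 fold changes of 0.14 and -0.05 in MCT vs Control and -0.03 and -0.06 in MCT_C75 vs MCT. Bmpr2, the gene most often mutated in heritable pulmonary hypertension, had 0.30 (SE 0.28) and -0.07 (SE 0.27), and its Control libraries stood at 2223 and 1143 CPM. Edn1, the endothelin-1 gene, had -0.19 and 0.04, Nos3, endothelial nitric oxide synthase, 0.04 and 0.32, and Acta2, smooth muscle actin, 0.26 and -0.12.

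The second comparison, the one the series title names, asked what differed when C75 was given with monocrotaline. Neutrophil genes were higher in MCT_C75 than in MCT lungs. Mmp8 rose by 2.41 (SE 0.21) on the log2 scale, from 12.1 ± 0.07 to 64 ± 7.32 CPM (n = 2 each), and Retnlg and S100a9 rose by 2.17 (SE 0.20) and 2.31 (SE 0.22). Il1b and Il1r2, the interleukin-1 beta gene and a decoy receptor gene for interleukin-1, rose by 2.33 (SE 0.31) and 2.45 (SE 0.37). Trem1, a receptor on myeloid cells, rose by 1.75 (SE 0.25), and H2-Q10, a class I histocompatibility gene expressed mostly in liver, rose by 1.95 (SE 0.23).

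edgeR called 17 genes, all higher in MCT_C75. The largest rises were Dhrs9 (2.52, SE 0.31), Il1r2, Rdh12 (2.42, SE 0.37), Mmp8, Il1b and Slfn4 (2.32, SE 0.23), with edgeR Benjamini-Hochberg adjusted p-values of 0.00926, 0.0379, 0.0434, 0.00194, 0.0178 and 0.00233. The others were S100a8, Clec4e, Clec4d, Cxcr2, Gm38525, Mgam and Ccr1, with log2 fold changes of 2.22, 2.30, 2.26, 2.07, 2.05, 1.96 and 1.59. No gene passed as lower in edgeR. DESeq2 called 122 genes, 117 higher and 5 lower, and limma-voom 18, and 859 genes had an unadjusted edgeR p under 0.05. Few or no calls remained when either MCT library was left out, and they became fewer without MCT_C75 replicate 2. Without MCT_C75 replicate 1 there were more calls, slightly more of them lower than higher in MCT_C75. Each of these fits leaves a group with 1 library. A replicate block, which only shares a number between groups, gave 10 calls, all higher.

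Of the 14 neutrophil genes, 8 rose, and 11 rose when adjusted over the list alone (median 2.10, camera adjusted p = 6.79e-21; adjusted p = 0.549 with an estimated correlation). Liver transcripts were higher by camera (median 1.35, adjusted p = 2.24e-05; adjusted p = 0.787 with an estimated correlation), with 0 of 10 members called over all genes and 7 higher when adjusted over the list alone. The liver median was 0.80 without MCT_C75 replicate 1 (adjusted p = 0.022) and 1.75 without MCT_C75 replicate 2. Alb, the serum albumin gene, was at 137 and 183 CPM in the MCT libraries and 675 and 391 CPM in the MCT_C75 libraries, but also at 102 and 309 CPM in Control, and Fgb, a fibrinogen chain, had a log2 fold change of 1.83 (SE 0.44). Cardiac muscle genes were lower by camera (median -0.64, adjusted p = 0.000267; adjusted p = 0.806 with an estimated correlation). That value came from MCT_C75 replicate 2, in which Myh6, the atrial myosin heavy chain, was at 0.206 CPM against 54 to 160 CPM in the other libraries, and without it the median was 0.17. None of the 14 members passed over all genes or over the list alone.

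Mesothelium genes were higher (median 1.14, camera adjusted p = 0.000902), as were replication-dependent histones (0.30, 0.000902), immediate early and heat shock genes (0.30, 0.00545) and monocytes and interstitial macrophages (0.38, 0.0123), while extracellular matrix genes were lower (-0.23, 0.0056), and each had an adjusted p = 0.787 with an estimated correlation. No member of these lists was called over all genes or over the list alone. The smallest p-values belonged to Bnc1 (2.83-fold) and Msln (log2 fold change 1.27, SE 0.44) of the mesothelium, Hspa1a (0.94), Junb (0.74), Treml4 (1.27), the linker histone gene Hist1h1e (0.51) and Ctgf (-0.55). Without MCT_C75 replicate 2 the camera adjusted p was 0.338 for mesothelium and for extracellular matrix genes, without MCT_C75 replicate 1 it was 0.463 for immediate early genes, and without MCT replicate 1 it was 0.293 for histones and 0.398 for monocytes. Leaving out 1 library also moved the medians, to 0.405 (MCT replicate 1) and 2.16 (MCT replicate 2) for mesothelium, 0.53 (MCT replicate 2) for histones, 0.08 (MCT_C75 replicate 1) and 0.60 (MCT_C75 replicate 2) for immediate early genes, 0.145 (MCT replicate 1) for monocytes, and -0.11 (MCT replicate 2) and -0.35 (MCT_C75 replicate 1) for extracellular matrix. Among the 31 other lists, smooth muscle contractile genes (-0.21, camera adjusted p = 0.0516), inflammatory cytokines and chemokines (0.42, 0.0718) and circadian clock genes (0.27, 0.0793) came closest. Fatty acid synthesis had a median of 0.05 (0.36), fatty acid oxidation 0.06 (0.649), cholesterol synthesis -0.16 (0.0963), glycolysis 0.15 (0.174), heritable pulmonary hypertension genes 0.01 (0.961), vasoactive mediators -0.03 (0.358) and endothelial cells 0.02 (0.92, mean -0.02).

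**Figure D2:**
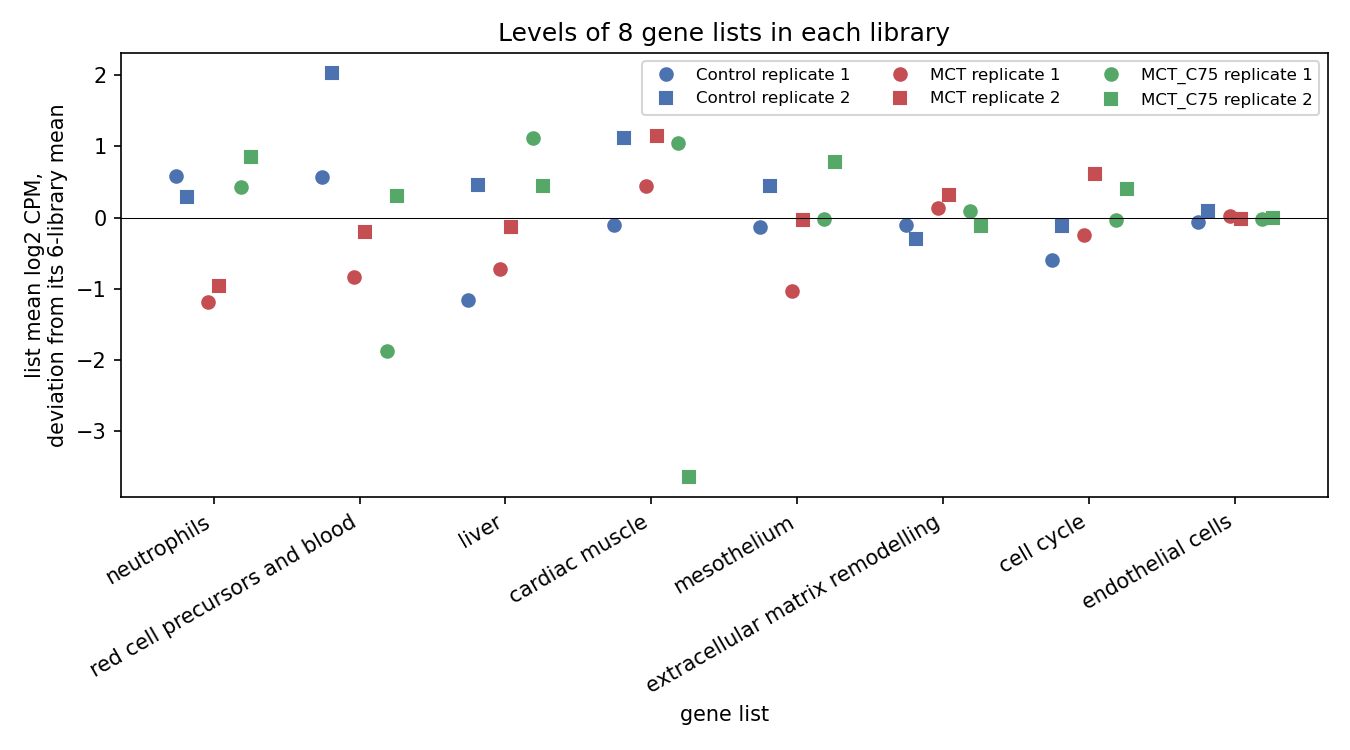
Mean log2 CPM of 8 gene lists in each of the 6 libraries, as a deviation from the list's mean over the libraries, with circles and squares for replicates 1 and 2. Neutrophil genes are lowest in the MCT libraries at -1.18 and -0.97, cardiac muscle genes stand at -3.65 in MCT_C75 replicate 2, and red cell genes spread from -1.88 to 2.03.

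The 2 comparisons share the MCT libraries, so opposite fold changes are expected by chance. All 11 genes that fell in MCT rose with C75, where independent lists would share 0.00799 genes. The 11 genes were Slfn4, Dhrs9, Clec4e, S100a9, S100a8, Mmp8, Clec4d, Cxcr2, Gm38525, Retnlg and Ccr1, and 6 of the 11 genes belonged to the neutrophil list. In MCT_C75 vs Control the 11 genes had a median log2 fold change of 0.03, with values from -0.25 to 0.30 and none past the threshold. Those genes were chosen for opposite changes in the same data, and the third fold change is the sum of the other 2. Small values here are therefore partly built in. In 50 simulations of unchanged groups that shared the MCT libraries, at most 2 genes were called in both with opposite signs. Up to 8 genes were called in a single simulated comparison, against 12 in MCT vs Control and 17 in MCT_C75 vs MCT in the data. Across all tested genes, which are not independent replicates, the fold changes correlated at -0.507 (simulated mean -0.496, from -0.517 to -0.467). The covariance was -0.249, against a simulated mean of -0.194 (from -0.207 to -0.176), a difference of -0.0549. The simulations drew each gene independently, whereas the neutrophil list had an estimated inter-gene correlation of 0.234. They also gave each gene the same dispersion in all groups. In the data, replicate differences against counting noise (chi-square per degree of freedom) were 148 in Control, 30.2 in MCT and 59.8 in MCT_C75. The count and the covariance lay outside the simulated values, and the correlation lay within them. Genes that move together and groups of unequal spread were not simulated, so this does not bound what chance gives for such genes or groups. With a separate MCT library in each comparison, replicate 1 against Control and replicate 2 against MCT_C75, the neutrophil medians were -1.84 and 2.19, and with the replicates exchanged -1.96 and 2.08, with no member called in these smaller fits.

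**Figure D3:**
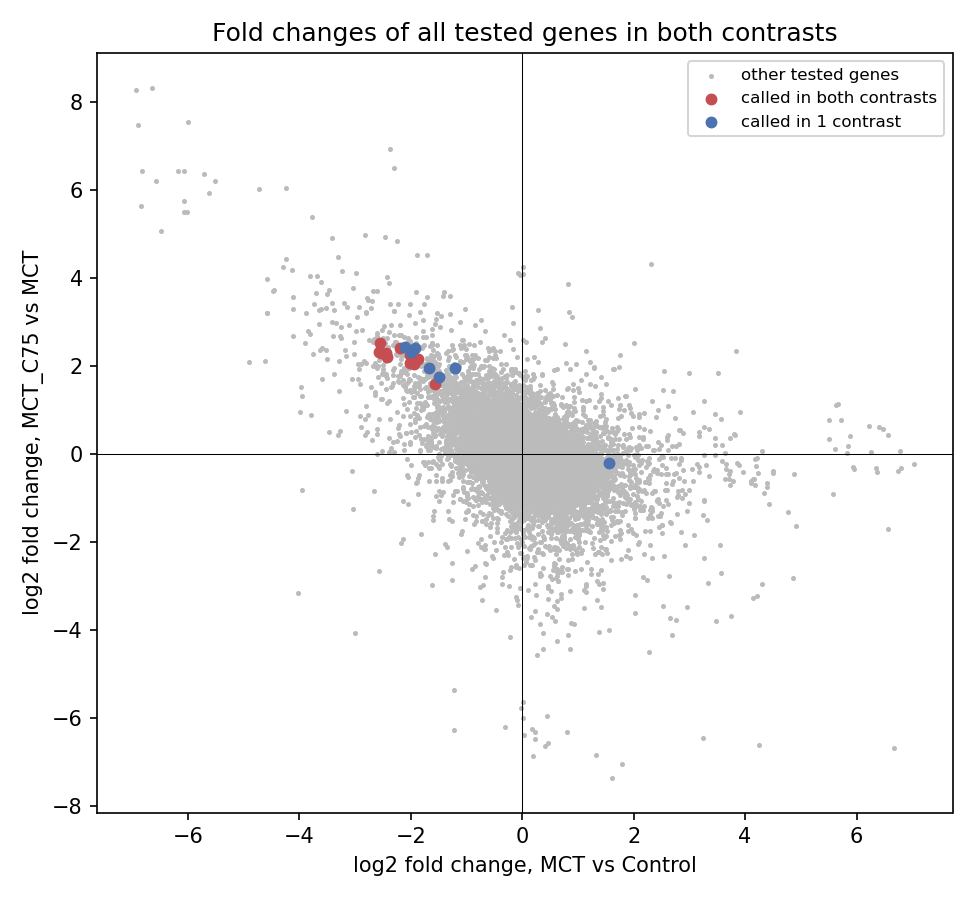
Log2 fold change of each of the 23399 tested genes in MCT vs Control (horizontal axis) and in MCT_C75 vs MCT (vertical axis), with the 11 genes called in both in red and those called in 1 comparison in blue. The downward slope of the grey cloud, with a correlation of -0.507, lies near the -0.496 of simulated unchanged groups that share the MCT libraries.

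The third comparison asked how far the MCT_C75 lungs stood from saline lungs. No gene passed, and the neutrophil list did not differ past the threshold (median 0.25, camera adjusted p = 0.29). Red cell transcripts were lower (median -2.15, camera adjusted p = 1.99e-07; adjusted p = 0.888 with an estimated correlation), with 0 of 11 members called over all genes and 6 lower over the list alone, and Hba-a1 and Alas2 at -2.96 (SE 0.63) and -2.40 (SE 0.47). The red cell median was -1.12 without Control replicate 2 (adjusted p = 0.0159), -1.17 without MCT_C75 replicate 1 and -3.54 without MCT_C75 replicate 2. Liver transcripts were higher (median 1.01, camera adjusted p = 0.000397; 2 of 10 members higher over the list alone), as were cell cycle genes (0.58, 0.00068) and replication-dependent histones (0.27, 0.00382). Cardiac muscle (-0.56, 0.00382), cholesterol synthesis (-0.21, 0.0144), T and NK cells (-0.23, 0.0245) and sex-linked genes (-0.22, 0.0255) were lower, with no member called over all genes, and all of these lists had an adjusted p = 0.888 with an estimated correlation.

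edgeR called 0 genes in this comparison, with 744 at an unadjusted p under 0.05, while DESeq2 called 3 and limma-voom 0. The smallest edgeR p-values belonged to Rnu1a1 (log2 fold change 1.37, SE 0.21), Alas2, Ntrk2, a neurotrophin receptor (1.11, SE 0.22), Snord15b, a small nucleolar RNA (1.32, SE 0.27), and Hba-a1, none past the threshold. Snord15b lies inside the gene Rps3 on the same strand, so the counts of the 2 could be shared. Among cell cycle genes Birc5 had 1.62 (SE 0.43) and Mki67 0.99 (SE 0.37), and among cholesterol synthesis genes Msmo1 had -0.61 (SE 0.19). Apoa1 and Alb of the liver list had 1.56 (SE 0.49) and 1.37 (SE 0.41), and Tsix of the sex-linked list -0.95 (SE 0.46). Tsix overlaps Xist on the opposite strand, and strand information of the libraries is not given, so the counts of the 2 could be shared. The sex-linked list holds both X-linked and Y-linked markers, so its direction as a whole is not a measure of sex. Without Control replicate 1, Control replicate 2 and MCT_C75 replicate 1, edgeR called 151, 73 and 6 genes. Without MCT_C75 replicate 2 or Control replicate 2 the cardiac median was 0.27 and 0.20, and without MCT_C75 replicate 1 that of T and NK cells was 0.01 and that of sex-linked genes -0.05 (camera adjusted p = 0.803). Without Control replicate 1 the medians were 0.37 for liver, 0.36 for cell cycle and 0.11 for histones, and without Control replicate 2 they were 2.33 for liver, 0.51 for histones and -0.06 for cholesterol synthesis. With 1 library left out the cell cycle median ranged from 0.23 to 0.84 and that of sex-linked genes from -0.39 to -0.05. Each of these lists lost its camera call in some of these fits.

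The series also set out to profile long non-coding RNAs, of which 4316 were tested. None passed edgeR's test in any comparison. In MCT vs Control 174 had an unadjusted p under 0.05, where chance gives 216, and DESeq2 called 4 and limma-voom 0. In MCT_C75 vs MCT the numbers were 161 by unadjusted p, 7 by DESeq2 and 0 by limma-voom, and in MCT_C75 vs Control 128, 0 and 0. The fixed list of known long non-coding RNAs, which includes H19, Meg3, Malat1 and Neat1, had medians of 0.03 (camera adjusted p = 0.826), -0.07 (0.0963) and -0.07 (0.29). Long non-coding RNAs were measured less precisely, with a median SE of 0.77 in MCT vs Control against 0.22 for protein-coding genes.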

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

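The fit without Control replicate 2 and MCT_C75 replicate 2 was chosen only after the results were seen, and all other alternatives before. The counts of genes called were 12 for MCT vs Control, 17 for MCT_C75 vs MCT, 0 for MCT_C75 vs Control and 11 for opposed changes. With DESeq2 they became 108, 122, 3 and 59, and without a filter on low counts 220, 278, 118 and 107. With an unadjusted p and a fold of at least 2 they were 536, 567, 429 and 173, and with only the 4 samples compared 7, 73, 0 and 6. A mean of at least 5 CPM gave 8, 8, 0 and 7, which tests fewer genes. Without the 2 libraries in doubt the counts were 521, 586, 1036 and 132, from fits that leave Control and MCT_C75 with 1 library each. With each library left out in turn the counts ranged from 0 to 379, 0 to 45, 0 to 151 and 0 to 57. A lone library is then assumed to vary like the other groups, but the groups did not vary alike. The chi-square of replicate differences against counting noise, per degree of freedom, was 148 in Control, 30.2 in MCT and 59.8 in MCT_C75. Leaving out a library of a more or less variable group changes the shared estimate of the spread. Whether this moved the counts was not tested, nor were other causes. Other scalings, limma-voom and an added fold of at least 2 stayed within 1.5 times of the main counts. A replicate block gave 11, 10, 0 and 6, of which 6 of the 11 in MCT vs Control, all lower, and 9 of the 10 in MCT_C75 vs MCT were among the genes called without it, and Rnu1a1 was not called. The replicate numbers did not pair the samples, since deviations of same-numbered samples correlated at 0.0753 for Control and MCT, -0.116 for Control and MCT_C75 and -0.002 for MCT and MCT_C75. The neutrophil median kept its sign in every alternative, from -2.11 to -1.35 in MCT vs Control and from 1.77 to 2.27 in MCT_C75 vs MCT, but no member was called when either MCT replicate was left out. No list call held with an estimated correlation, 0 of 26. Groups of 2 libraries leave that version little power, so it cannot tell whether correlation alone removes a call. For neutrophils its unadjusted camera p was 0.0209 in MCT vs Control and 0.0141 in MCT_C75 vs MCT. Among other settings, 233 list values kept direction and call, 46 lost the call alone and 7 reversed. The cardiac muscle median became 0.1664 without MCT_C75 replicate 2 and 0.1661 without the 2 libraries in doubt in MCT_C75 vs MCT, and 0.2688 and 1.153 in MCT_C75 vs Control. The last of these passed as higher (camera adjusted p = 0.000502). The median was -4.4203 and -4.2688 in these comparisons without MCT_C75 replicate 1. Without Control replicate 2 it was 0.2032 in MCT_C75 vs Control, and immediate early and heat shock genes in MCT vs Control became 0.0714 without Control replicate 1 and -0.4126 without MCT replicate 2. T and NK cells reached 0.0143 without MCT_C75 replicate 1 and -0.534 without MCT_C75 replicate 2 in MCT_C75 vs Control, and Bmpr2 became -0.43 there without the 2 libraries in doubt and passed as lower (edgeR adjusted p = 0.0493); the cause was not tested. For called named genes 170 values kept their call and 51 lost it, and for the others 1205 stayed without a call, of which 34 in 21 results changed sign, and 104 passed.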

Other observations

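Apart from camera and the count over the list alone, the tests in this part were chosen only after the results they measure had been seen. Some genes of the circadian clock, a list fixed in advance that did not pass camera as a whole (adjusted p = 0.961 in MCT vs Control and 0.0793 in MCT_C75 vs MCT), had values in MCT apart from those of both other groups. Npas2, an activator of the clock, was at 5.96 and 4.85 CPM in the Control libraries, 13.6 and 9.16 in MCT, and 4.2 and 4.56 in MCT_C75. Its output gene Dbp was at 7.8 and 10.5, 5.56 and 5.35, and 10.7 and 13.2 CPM in the same order, and the repressor Nr1d2 at 153 and 155, 93.7 and 110, and 141 and 171 CPM. None passed over all genes in edgeR. Adjusted over the list alone, 1 member was higher and 1 lower in MCT vs Control, and 4 were higher and 2 lower in MCT_C75 vs MCT.

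Igha, the immunoglobulin A heavy chain, had a log2 fold change of -1.06 (SE 0.19) in MCT vs Control, and Slc2a3, a glucose transporter of leukocytes, had -1.32 (SE 0.21), neither past the threshold in edgeR. Ntrk2 was at 6.13 and 5.38 CPM in Control, 12.1 and 12.3 in MCT and 11.6 and 13.1 in MCT_C75.

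The fall of neutrophil genes in MCT and their higher level in MCT_C75 was weighed against 2 technical explanations. If less blood had been left in the MCT lungs than in the MCT_C75 lungs, red cell genes should also be higher in MCT_C75. Their list mean differed by -0.27 log2 units, with a 95% interval from -3.78 to 3.24 that includes the 1.71 of the neutrophil list. In MCT vs Control both lists fell, with medians of -2.26 for red cells and -1.94 for neutrophils, as less blood in MCT would give. In contrast, MCT_C75 replicate 1 had a red cell mean of -1.88 from the mean of all libraries, below both MCT libraries (-0.83 and -0.20). Its neutrophil mean was 0.42, against -1.18 and -0.97 in MCT. MCT_C75 replicate 2 stood at 0.31 for red cells and 0.85 for neutrophils. The explanation stays open because the libraries vary too much. If the MCT lungs had been taken at another time of day, clock genes should set them apart, a score made after clock genes had been seen to differ. Evening-phase minus morning-phase genes differed by -0.86 log2 units between MCT and the other 4 libraries, and both MCT libraries lay outside the range of the others, -0.27 to 0.40, as 2 of 15 orders would by chance (0.133). The MCT_C75 libraries, at 0.40 and 0.29, also lay apart from the Control libraries, at -0.13 and -0.27, and time of day and group cannot be told apart without collection times, and an effect of monocrotaline and C75 on lung neutrophils also stays open, as untested.

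Cardiac muscle genes were lowest in MCT_C75 replicate 2, by unequal factors: against the mean of the other 5 libraries Myh6 was 567-fold lower, Tnnt2 6.69-fold, Ryr2 3.14-fold and Actc1 1.99-fold. All 14 of the 14 list members were lowest in that library, and the skeletal muscle and club cell lists were also lowest there, at -1.49 and -0.87 from the mean of all libraries. That count restates the pattern, so it decides nothing about little heart muscle in that tissue piece, which stays open. A loss of cardiac transcripts with C75 in both treated libraries is argued against by MCT_C75 replicate 1, whose list mean lay 0.40 log2 units above that of the Control and MCT libraries.

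Small nuclear and nucleolar RNAs were seen only after the results and were not tested as a set. In MCT vs Control 72 of 108 had a positive log2 fold change (median 0.36), as did 29 of the 33 at 1 CPM or more (median 0.70), and Rnu1a1 alone passed. In MCT_C75 vs Control 26 of the 33 were positive (median 0.42), with the MCT_C75 libraries apart at 0.29 and -0.21 from the mean of all libraries. A positive majority in MCT vs Control was not particular to these RNAs. At 1 CPM or more it was also found for 452 of 681 genes of the deposited type TEC and 547 of 942 of type lncRNA. By contrast, 6321 of 13958 protein-coding genes and 78 of 190 pseudogenes were positive there. A candidate explanation is that RNA molecules under 250 bases of every kind were retained more in the MCT libraries. Nuclear transfer, Y and Bc1 RNAs under that length, most of them under 1 CPM, had a median of 0.44. The 95% bootstrap interval, from 0.16 to 0.72, reaches below the 0.18 set as the bound. It resampled genes and not libraries, so it leaves out the spread between libraries. The set stood at -0.475 and 0.257 log2 units from the mean of all libraries in Control, and at 0.258 and 0.354 in MCT. By deposited gene length, 7SK, 7SL, RNase MRP and RNase P were longer and had a median of -0.04. Vaultrc5 had 1.46 with a deposited length of 345 bases, but the length of its RNA was not measured, so it decides nothing. The explanation stays open. A first version of the test took every other gene under 350 bases and gave a median of -0.06, but 15 of its 60 genes were immunoglobulin segments and 14 microRNA loci, so it was replaced after its value was seen, and an effect of monocrotaline stays open, as untested.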
